A study of Mus musculus with 2 samples.

How the data were processed

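H3K4me2 was measured by chromatin immunoprecipitation and sequencing in whole hearts of embryonic day 15.5 B6NCrl mice of mixed sex, in 1 group of 2 biological replicates, which were pools of 78 and 62 embryos per the labels. The files held 4 peak lists in narrowPeak format, which per the file headers and the notes deposited with them were called on each replicate, called on the reads of both replicates, or selected as replicated from the pooled list and the lists of the replicates. Per those notes each list came from filtered alignments to mm10 with input control files. The aligner, the read filters, the peak caller and the rule that kept a peak in the replicated list are not given in the sources used here. The input control was not analysed here. Read depth was unknown, since no file gave read counts, and no interval or limit that needs it is printed.

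The authors' score of each peak was not used. The fold of each peak, a ratio of enrichment over control in the deposited lists, was used as the authors gave it, and column meanings were taken from the format. The deposited −log10 p-value of each peak had a minimum of 2.01 in replicate 1 and 2.03 in replicate 2, so the lists were loose. By the deposited −log10 q-value, q was over 0.05 for 3.56% of the peaks of replicate 1, 2.28% of those of replicate 2, 1.33% of the pooled and 0.0345% of the replicated peaks. The summit position was not used. Peak values describe peaks within a list, since folds were not scaled between lists. All 46362 replicated peaks were identical to a pooled peak. In each of both replicates, peaks covered at least 50% of 38996 of them (84.1%) and at least 1 base of 42386 (91.4%).

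Genes were those of GENCODE release M21 on GRCm38, whose chromosome names and lengths were compared with the peak coordinates of mm10 and contained all of them. Protein-coding genes on the chromosomes numbered 21911, with 27 symbols on more than 1 gene model. Positions are 1-based. Of the symbols in the fixed lists 1, Ahsp, had no protein-coding gene in the annotation and was left out. Overlaps were counted with bedtools 2.31.1, sequences were read with pysam 0.24.0, and tests were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Plots were drawn with matplotlib 3.10.9. The seed was 1.

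A peak of 1 replicate was shared when at least 50% of its bases lay under peaks of the other. The chance level came from 100 random placements on the same chromosomes. Fold was compared between replicates by Spearman's rho and Pearson's r on the log2 scale over replicated peaks, each given the highest fold among the peaks of a replicate that overlapped it. The spread set against changes in rho was a jackknife over chromosomes, with a standard error of 0.00242, which was not in the original plan. A peak was near a TSS within 1000 bases either side of a protein-coding TSS, then assigned to exon, intron or intergenic in that order. A gene had a promoter peak when a replicated peak lay within 1000 bases of any of its TSSs. Breadth was the number of bases under peaks within 5000 bases either side of the 5'-most TSS, and a domain was a run of peaks joined over gaps of up to 1000 bases.

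The 25 gene lists were compared with other protein-coding genes by two-sided Fisher's exact tests on promoter peaks. Breadth of the marked members, for lists with at least 5, was compared with 10000 random lists of marked genes matched on gene-length decile by a two-sided permutation test. The 18 consensus sequences were counted in the central 500 bases of distal peaks and of control regions of the same chromosome, width and GC content (bins of 5 percentage points) outside all peak lists, by two-sided Fisher's exact tests. Of 27571 distal peaks 26507 had a control. P-values were adjusted by the Benjamini-Hochberg method within each family of lists or motifs, with a threshold of 0.05. Each test was repeated in the list of each replicate.

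The lists, the consensus sequences, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named up to 4 members of each list with the most covered bases, which for lists of other cells and tissues had to carry a promoter peak, the heart list members without a promoter peak, the 20 genes with the widest domain, and the 5 genes of each replicate with the highest fold among those marked in that replicate alone. Marks at near-identical globin genes were treated as uncertain. The lists covered cardiac transcription factors, sarcomere and Z-disc, calcium handling and ion channels, conduction system, endothelium and endocardium, epicardium, fibroblasts and valve mesenchyme, smooth muscle and pericytes, oxidative metabolism, glycolysis, cell cycle, housekeeping, erythroid cells, macrophages and leukocytes, neural crest and peripheral nerve, lung and foregut epithelium, liver, central neurons, skeletal muscle, kidney and gonad, germ cells, pluripotency, anterior Hox, posterior Hox and olfactory receptors.

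The alternatives chosen beforehand were a fold of at least 3, a −log10 p of at least 5, the pooled list, each replicate without the other, overlaps of 1 base, 25%, 75% and 50% reciprocal, TSS windows of 500 and 2500 bases, 1 TSS per gene, breadth windows of 2 and 10 kb, random lists with no matching or matched on GC content, whole peaks and no GC matching for motifs, and −log10 p in place of fold for the correlation. The alternatives added after the data were seen were genes with no other protein-coding TSS within 2 kb or 10 kb, random lists matched on the CpG ratio of 1 kb around the TSS, and regions with under 10% of repeat-masked bases.

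The procedures were tested on simulated data before use. For the share of shared peaks, 60.1% of 56776 peaks were left in place and 60.4% were called shared. For the correlation over 46362 peaks, a rho of 0.871 was put in and recovered. For promoter lists over 21911 genes, 3% of random lists of 20 had an unadjusted p under 0.05, 0 passed the adjusted threshold, and all lists with 20 marked members or with 6 of 20 marked members were called. For breadth over 15216 genes, 6.5% of random lists had an unadjusted p under 0.05 and 1 passed the adjusted threshold. Lists with 16 of 20 members from the wider part of the genes were called in 20% of cases, and lists with all 20 from the widest 25% in 100%, a case added after the low rate of the former was seen. For motifs in 20000 sequences, 600 planted sites gave an excess of 552 sequences, and 0 other motifs were called. Both sets were uniform random bases, so the 0 does not cover calls that arise from differences in base or CpG content between real regions.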

Results

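Histone H3 dimethylated at lysine 4 (H3K4me2), a chromatin mark of promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in whole hearts of mouse embryos at embryonic day 15.5. The labels gave 1 group with 2 biological replicates, and no other group. Replicate 1 was a pool of 78 embryos and replicate 2 a pool of 62 embryos, all B6NCrl and of mixed sex. The authors' peak list of replicate 1 held 56790 peaks over 54.8 Mb, and that of replicate 2 held 61272 peaks over 60.5 Mb. A list called on the pooled reads held 62505 peaks over 65.3 Mb. The authors' replicated list held 46362 peaks over 60.8 Mb, with a median width of 895 bases and a median fold enrichment of 8.03. All coordinates are those of mm10. Read depth is unknown, because no file gave read counts, so a place without a peak is one where no peak was listed. Genes, peaks and regions are the units of every test, not replicates, and the p-values describe these pooled hearts.

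The strongest peaks were found in both heart pools, and the weak ones were often found in 1 pool alone. The domain at Hand2, a transcription factor needed for the right ventricle, and those at Nkx2-5 and Tbx5, regulators of early heart formation, were in both lists. At Hand2 the promoter peak had a fold of 23.0 in replicate 1 and 32.3 in replicate 2. At Nkx2-5 it had 17.1 and 20.7, and at Tbx5 21.1 and 22.2. All peaks near a TSS had a median fold of 19.1 in replicate 1 and 23.8 in replicate 2. The promoter peaks at Nkx2-5 and Tbx5 were thus not among the strongest. A peak was counted as shared when at least 50% of its bases lay under peaks of the other replicate. By that measure 79.3% of the peaks of replicate 1 and 67.6% of those of replicate 2 were shared, a mean of 73.5% ± 8.27 (SD). Both values come from 1 overlap read in 2 directions, so the SD is not a spread of independent replicates. Random placements of the other list gave 2.22% ± 0.0687 and 2.00% ± 0.0647 (SD, 100 placements). The median fold was 7.95 for shared and 3.10 for unshared peaks of replicate 1, and 10.8 and 3.30 for those of replicate 2. Among peaks with a fold of 20 or more, 99.99% and 99.95% were shared, against 43.1% and 25% of those with a fold under 3.

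**Figure D1:**
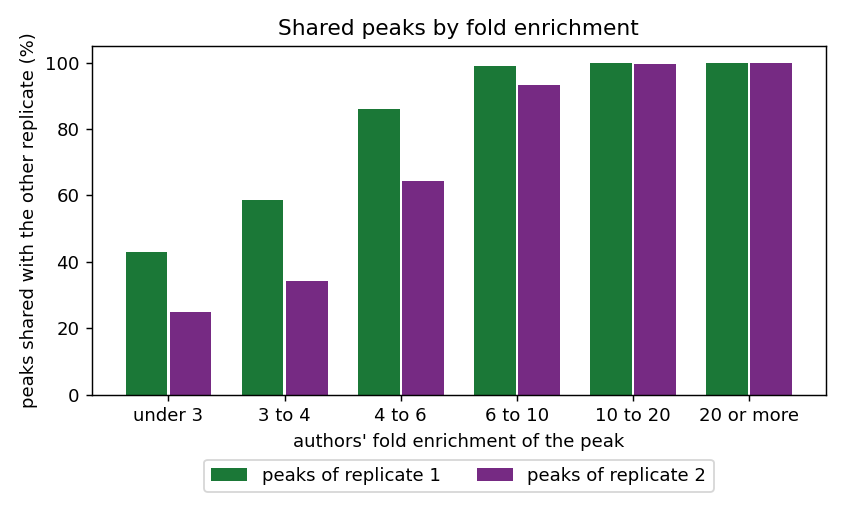
Percent of the peaks of replicate 1 (green) and of replicate 2 (purple) that were shared with the other replicate (y axis), in bins of the authors' fold enrichment of the peak (x axis). The share was 43.1% and 25% in the lowest bin, and 99.99% and 99.95% in the highest.

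Across 42386 replicated peaks with a peak in each replicate, the authors' folds had a Spearman's rho of 0.912 and a Pearson's r of 0.933 on the log2 scale. The other 3976 replicated peaks lacked a peak in at least 1 replicate. The authors' folds, which were not scaled between lists, were higher in replicate 2 by a median of 0.25 on the log2 scale (SD 0.48 across peaks), and 81.1% of the peaks lay within 1.5-fold of that shift. The correlation is across peaks, which are not independent, so it has no p-value.

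Promoters carried the widest and strongest peaks, and most of the remaining peaks lay in introns or between genes. Of the replicated peaks, 40.5% lay within 1 kb of a transcription start site (TSS) of a protein-coding gene, 5.54% in other exons, 25.5% in introns and 28.4% between genes. The share near a TSS was 37.1% in replicate 1 and 34.6% in replicate 2, a mean of 35.8% ± 1.78 (SD, n = 2). Random placement gave 6.11% ± 0.113 (SD, 100 placements). The 18778 peaks near a TSS had a median width of 1892 bases and a median fold of 26.1. The 27584 distal peaks had a median width of 635 bases and a median fold of 4.83. Of all bases under replicated peaks, 64.9% were in peaks near a TSS.

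A promoter peak, within 1 kb of any annotated TSS, was present at 15216 of 21911 protein-coding genes (69.4%). Replicate 1 gave 15178 and replicate 2 gave 15392 such genes, a mean of 69.8% ± 0.691 (SD, n = 2). Both replicates marked 15116 genes, 97.8% of those marked in either. Replicate 1 alone marked 62 genes and replicate 2 alone 276. The replicate 1 genes with the highest folds were Il13, an interleukin gene, at 25.8, Apof, which encodes an apolipoprotein, at 20.7, Ccdc183 at 4.95, Scg2, a secretogranin gene, at 4.92, and Ppef2 at 4.74. The replicate 2 genes with the highest folds were Plin1, which encodes a lipid droplet protein, at 49.4, 1700086D15Rik at 45.0, Gckr, which encodes the glucokinase regulator, at 42.4, Tchh at 36.8, and Stac3, a skeletal muscle gene, at 27.8. Il13, Plin1, Gckr and Tchh also had a promoter peak in the replicated list, and the other named genes had none there. Within 5 kb of any TSS, but beyond 1 kb, the other replicate had peak bases at 20 of the 62 genes and at 104 of the 276. Of the named genes it had 1561 at Il13, 1347 at Apof, 1982 at Ccdc183, 1296 at Plin1, 2270 at 1700086D15Rik, 1911 at Gckr, 3918 at Tchh and 2157 at Stac3, and 0 at Scg2 and Ppef2.

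Genes of most of the heart's own cell types were almost fully marked at their promoters. A promoter peak was present at all 22 cardiac transcription factors, at all 26 genes of the sarcomere and Z-disc and at all 13 genes of the conduction system, and at 17 of 18 genes of calcium handling and ion channels. The exception was Sln, which encodes sarcolipin, an inhibitor of the calcium pump of the sarcoplasmic reticulum: it had no peak base within 5 kb in either replicate. All 23 endothelial and endocardial genes, all 15 genes of fibroblasts and valve mesenchyme, all 13 of smooth muscle and pericytes and all 23 of oxidative and fatty acid metabolism were marked. In both replicates each of these lists had the same percent of marked members. Of 13 epicardial genes 10 were marked. Msln, Upk3b and Muc16, genes of mesothelial surface proteins, had no promoter peak in the replicated list, and 9 members were marked in replicate 1 and 11 in replicate 2.

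The lists were fixed before the data were examined, as were the motifs, the tests and the rule for named genes, and each list was tested against all other protein-coding genes by a two-sided Fisher's exact test. Of 25 lists 18 passed an adjusted p of 0.05, 13 of them higher and 5 lower than other genes. Adjusted p was 0.00176 for cardiac transcription factors, 0.000671 for sarcomere and Z-disc, 0.0307 for calcium handling and ion channels, 0.0222 for the conduction system, 0.00112 for endothelium and endocardium, 0.0162 for fibroblasts and valve mesenchyme, 0.0222 for smooth muscle and pericytes, and 0.00112 for oxidative metabolism. Epicardium did not pass the exact test (adjusted p = 0.766). With 1 TSS per gene, adjusted p was 0.0708 for calcium handling and ion channels. Against random lists of the same CpG content the conduction system could not be called higher, since those lists reached 100% as well. Cardiac transcription factors passed narrowly against such lists, which had 86.3% on average and a 95% range of 77.3% to 95.5% (adjusted permutation p = 0.0491). The other heart lists called above kept an adjusted permutation p of 0.025 or less.

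Genes used by most cells were marked in full as well. All 16 genes of glycolysis, all 20 of the cell cycle and all 25 housekeeping genes had a promoter peak in each replicate. Their adjusted p by Fisher's exact test was 0.0108, 0.0025 and 0.00098. With 1 TSS per gene, adjusted p for glycolysis was 0.161. Random lists of the same CpG content as the cell cycle and housekeeping lists reached 100% as well, so these could not be told apart from them.

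Genes of blood cells, liver, germ cells and olfactory neurons were marked less often than other genes. Of 16 macrophage and leukocyte genes, Laptm5, which encodes a lysosomal protein of leukocytes, and Cd14, a receptor for bacterial lipopolysaccharide, were the 2 with a promoter peak. Ptprc, the pan-leukocyte antigen, and Csf1r, the receptor that macrophages need, had none. Of 13 erythroid genes 5 were marked, among them the transcription factors Tal1, Nfe2 and Klf1 and the transferrin receptor Tfrc. The alpha-globin and beta-globin genes had no promoter peak, but are uncertain because their copies are nearly identical. Of 19 liver genes 5 were marked, among them Foxa1, Foxa2 and Foxa3, transcription factors of endoderm, and Trf, which encodes transferrin. Foxa3 and Trf have a TSS of another gene within 2 kb. Alb, the albumin gene, had no promoter peak. Of 13 germ cell genes Dazl and Ddx4, which encode RNA-binding proteins, were the 2 with a peak, and of 1134 olfactory receptor genes 6 had one, with Olfr94 the widest. Ptprc, Csf1r, Alb and the globin genes were chosen after their values were seen.

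Adjusted p by Fisher's exact test was 4.7e-05 for macrophages and leukocytes, 0.0428 for erythroid genes and 0.000671 for both liver and germ cells, and the olfactory receptor list, at 0.529% against 73.2% of other genes, also passed. Replicate 1 marked 3 and replicate 2 marked 4 macrophage genes. The erythroid call of the exact test was lost in replicate 2 (6 members, adjusted p = 0.0971), with 1 TSS per gene (adjusted p = 0.0708) and among genes with no other TSS within 2 kb (adjusted p = 0.104). Against random lists of the same CpG content the erythroid, liver and macrophage lists were no longer called. The erythroid share of 38.5% was near the 42.7% of such lists. Liver, at 26.3% against 50.9%, and macrophages, at 12.5% against 33.0%, stayed lower without passing (adjusted permutation p = 0.0696 and 0.191).

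Promoter peaks were also present at many genes of other tissues, although 6 of the 8 lists below did not pass the test against other genes. The share of all protein-coding genes was 69.4%. Central neuron genes had a promoter peak at 20 of 22 members, among them Dlx2, Emx1, Eomes and Neurog2, transcription factors of the forebrain and of neuron formation. Neurod6 and Slc17a6, a neuronal transcription factor and a vesicular glutamate transporter, were the 2 without a peak and were chosen after their values were seen. All 15 anterior Hox genes were marked, and 13 of 16 posterior Hox genes. Of 14 genes of lung and foregut epithelium 11 were marked, among them Shh, a secreted signal, and Nkx2-1, Sox2 and Grhl2, transcription factors of epithelia. Of 12 genes of kidney and gonad 8 were marked, with Foxl2, Lhx9, Six2 and Pax2 the widest. Skeletal muscle genes were marked at 11 of 20, with Mylpf, Ckm, Actn3 and Acta1 the widest, but the first 3 have a TSS of another gene within 2 kb. Neural crest and peripheral nerve genes were marked at 6 of 10, with Foxd3, Phox2a, Erbb3 and Ascl1 the widest, and pluripotency genes at 7 of 11, with Klf4, Esrrb, Utf1 and Lin28a the widest.

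Anterior Hox genes (adjusted p = 0.0162) and central neurons (adjusted p = 0.0478) passed Fisher's exact test. Neural crest (0.602), lung (0.65), skeletal muscle (0.292), kidney and gonad (0.766), pluripotency (0.766) and posterior Hox (0.524) did not, each given as its adjusted p. With a TSS window of 500 bases skeletal muscle was called lower by the exact test (45%, adjusted p = 0.0424). The central neuron call of the exact test was lost in replicate 2 (adjusted p = 0.0513), with a TSS window of 500 bases (0.138) and with 1 TSS per gene (0.243). In a permutation test against random lists of the same CpG content central neurons were not called (0.413), and posterior Hox genes, at 81.25%, were below the matched lists (adjusted p = 0.0491). The lists matched to anterior Hox genes reached 100% as well, so that list could not be told apart from them. Hox genes lie in clusters, and these tests treat neighbours as independent.

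**Figure D2:**
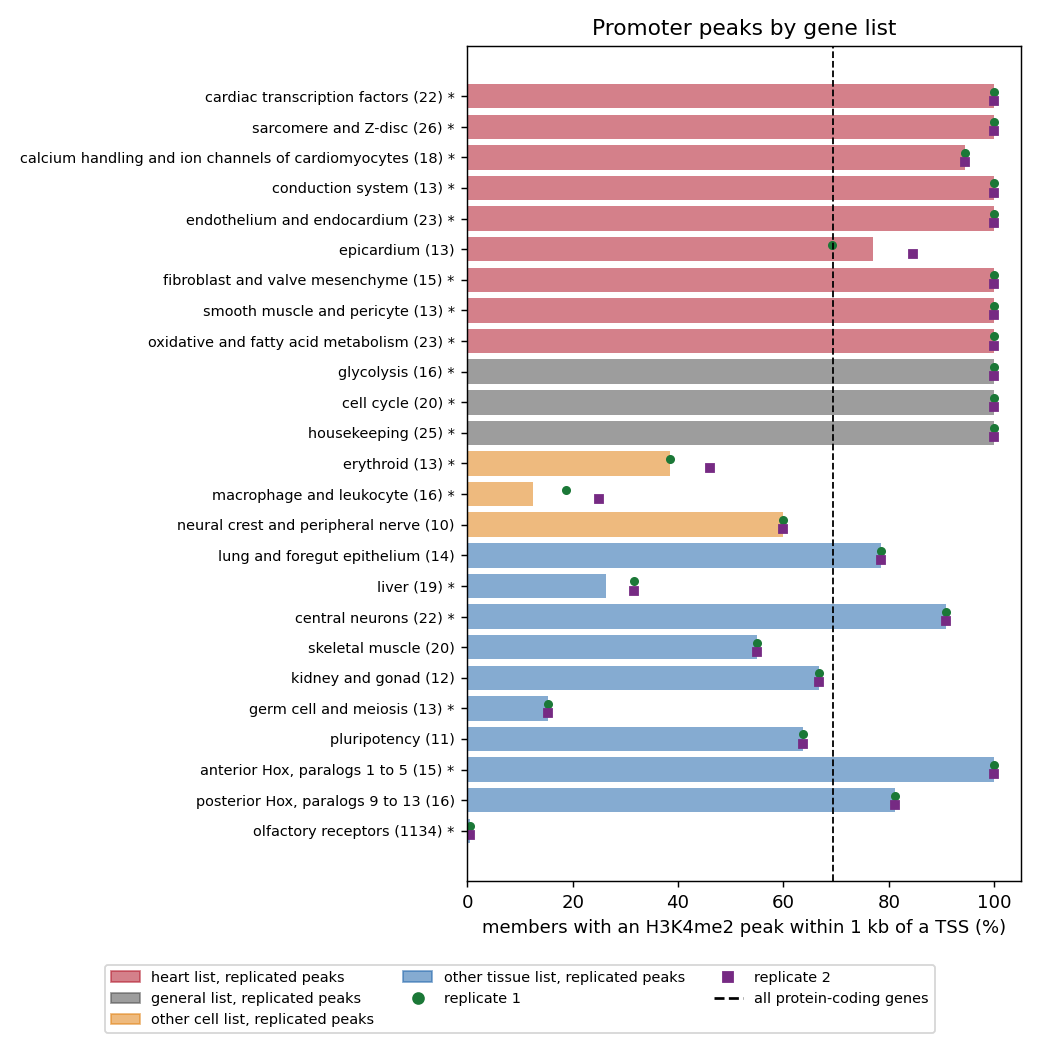
Percent of the members of each gene list with an H3K4me2 peak within 1 kb of a TSS (x axis), with bars for the replicated list, green circles for replicate 1, purple squares for replicate 2, list sizes in brackets and an asterisk where adjusted p was under 0.05. The dashed line is the share of all protein-coding genes, 69.4%, and 11 lists reach 100%.

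The mark spread far beyond the promoter at genes that build the heart. It covered a median of 7117 bases of the 10001 bases centred on the 5'-most TSS of the marked cardiac transcription factors, against a median of 2590 in random lists of marked genes of similar length. Mef2d, a transcription factor of muscle genes, had 10001 bases covered in the replicated list (9910 ± 129 in the replicates, SD, n = 2), Gata6 had 10001 (9713 ± 407), Hand2 had 9944 (9913 ± 124) and Tbx20 had 9209 (8775 ± 294), all of them regulators of cardiac development. Sarcomere and Z-disc genes had a median of 5695 bases. Actc1, cardiac actin, had 9582 (9388 ± 15.6), Myh7, the main ventricular myosin heavy chain of the mouse fetus, had 9050 (8155 ± 14.1), Tnnc1, cardiac troponin C, had 8378 (8230 ± 155) and Mybpc3, myosin-binding protein C, had 7809 (7349 ± 490). Genes of calcium handling and ion channels had a median of 5610 bases, with 6700 (6546 ± 45.3) at Jph2, which holds the plasma membrane to the sarcoplasmic reticulum, 6689 (6688 ± 36.8) at Gja1, which encodes connexin 43, 6604 (6276 ± 90.5) at Kcnj2 and 6522 (6011 ± 19.1) at Kcnh2, both potassium channels.

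Marks were also wider than at other marked genes in the lists of the conduction system, of endothelium and endocardium and of fibroblasts and valve mesenchyme. The smooth muscle list lay above its random lists (median 2570 bases) but missed the threshold (adjusted permutation p = 0.0526), and epicardium did not pass. Conduction system genes had a median of 4598 bases, with 9429 at Id2, 8697 at Irx3, 8242 at Tbx2 and 7541 at Tbx3, all transcriptional regulators. Endothelial and endocardial genes had a median of 4174 bases, with 8857 at Dll4, a Notch ligand of arteries, 7890 at Fli1, 7783 at Nfatc1, which valve formation needs, and 7332 at Sox7. Fibroblast and valve genes had a median of 4349 bases, with 8585 at Pdgfra, a growth factor receptor of fibroblasts, 7629 at Col1a1, a collagen gene, 6229 at Sox9 and 5447 at Scx. At Col1a1 the replicates differed more, with 5166 and 6893 bases. Smooth muscle and pericyte genes had a median of 3600 bases, with 5560 at Cspg4, 4947 at Pdgfrb, 4840 at Notch3 and 4354 at Smtn. Epicardial genes had a median of 2161.5 bases, although Wt1, a regulator of the epicardium, had 8607, Tbx18 had 6457, Tcf21 had 4733 and Sema3d had 2572.

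Metabolic and general genes were also wider than other marked genes. Oxidative and fatty acid genes had a median of 4642 bases, with 6255 at Esrra and 6016 at Esrrg, nuclear receptors that drive mitochondrial genes, 6122 at Fabp3, a fatty acid binding protein, and 5943 at Cpt1b, which admits fatty acids to mitochondria. Glycolysis genes had a median of 4404.5 bases, with 7566 at Eno3, 7208 at Gpi1, 6501 at Slc2a1 and 6021 at Pkm. Cell cycle genes had a median of 3968.5 bases, with 8207 at Ccnd2, 6660 at Ccnd1, 5481 at Mcm2 and 5158 at Ccnd3. Housekeeping genes had a median of 3748 bases, with 7222 at Ubc, 6879 at Actb, 6514 at Gapdh and 5348 at Polr2a. Tnnc1, Scx, Cspg4, Fabp3, Cpt1b and Ubc have a TSS of another gene within 2 kb.

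A list's median was tested against 10000 random lists of marked genes matched on gene length, by a two-sided permutation test. Of 23 lists with at least 5 marked members 15 passed, 11 wider and 4 narrower. The permutation p of cardiac transcription factors, sarcomere, calcium handling, endothelium and oxidative metabolism was 0.0002, the smallest that 10000 lists can give (adjusted p = 0.000767). Adjusted p was 0.00209 for the conduction system, 0.00153 for fibroblasts, 0.00131 for glycolysis, 0.00345 for the cell cycle and 0.00559 for housekeeping genes. Smooth muscle (adjusted permutation p = 0.0526, and 0.0377 in replicate 2) and epicardium (adjusted p = 0.428) did not pass. Smooth muscle passed with a fold of at least 3, with a −log10 p of at least 5, in the pooled list and with GC or CpG matching. Within 2 kb of the TSS the calls of calcium handling, conduction system, endothelium, glycolysis and housekeeping genes were lost, and among genes with no other TSS within 10 kb those of oxidative metabolism and housekeeping genes.

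Marks were narrower than at other marked genes in the lists of skeletal muscle, pluripotency, posterior Hox and olfactory receptor genes, and wider in that of anterior Hox genes. Skeletal muscle genes had a median of 1054 bases, with 2110 at Acta1, skeletal actin, where the replicates had 829 and 1937. Pluripotency genes had a median of 1049 bases, with Klf4 at 5242 and Esrrb at 2037. Posterior Hox genes had a median of 1305 bases (860 in replicate 1 and 1011 in replicate 2), with 2505 at Hoxd13 (1594 and 2683), 2109 at Hoxd11 (1360 and 2103), 1833 at Hoxb9 (1765 and 1835) and 1658 at Hoxa9 (736 and 2696). The 6 marked olfactory receptors had a median of 572. Anterior Hox genes, which pattern the hindbrain, neck and upper trunk, had a median of 4125 bases, with 8462 at Hoxa2, 6191 at Hoxb2, 6039 at Hoxa1 and 5900 at Hoxa3. Central neuron genes had a median of 2488.5 bases, with 3362 at Dlx2, 3191 at Emx1, 3069 at Eomes and 2957 at Neurog2.

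Adjusted permutation p was 0.00153 for skeletal muscle, 0.00389 for pluripotency, 0.00184 for posterior Hox, 0.000767 for olfactory receptors and 0.00797 for anterior Hox genes. Central neurons (0.769), neural crest (0.769), erythroid (0.774), lung (0.961), liver (0.915) and kidney and gonad (0.823) did not pass, each given as its adjusted p. The liver median was 2697 bases in the replicated list, but 1917 in replicate 1 and 1764.5 in replicate 2, and in the pooled list liver was called narrower. The anterior Hox median was 2953 bases in replicate 1 (adjusted permutation p = 0.262) and 5262 in replicate 2, and within 2 kb it was 2226 bases, under the median of the random lists but not called (adjusted permutation p = 0.836). Hox genes lie in clusters and share windows: Hoxd3 and Hoxd4 have TSSs 2 bases apart and 1865 covered bases each. The 5'-most TSS of some lies at another paralog. That of Hoxa3, with 5900 covered bases, lies between those of Hoxa6 and Hoxa7. That of Hoxc5 lies 647 bases from that of Hoxc10, a posterior gene, and both had 548 covered bases. Random lists draw genes independently, so both Hox p-values rest on fewer independent places than genes. The call was lost for skeletal muscle and pluripotency within 10 kb and for olfactory receptors against lists of the same GC content (adjusted permutation p = 0.1) or CpG ratio (0.169).

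**Figure D3:**
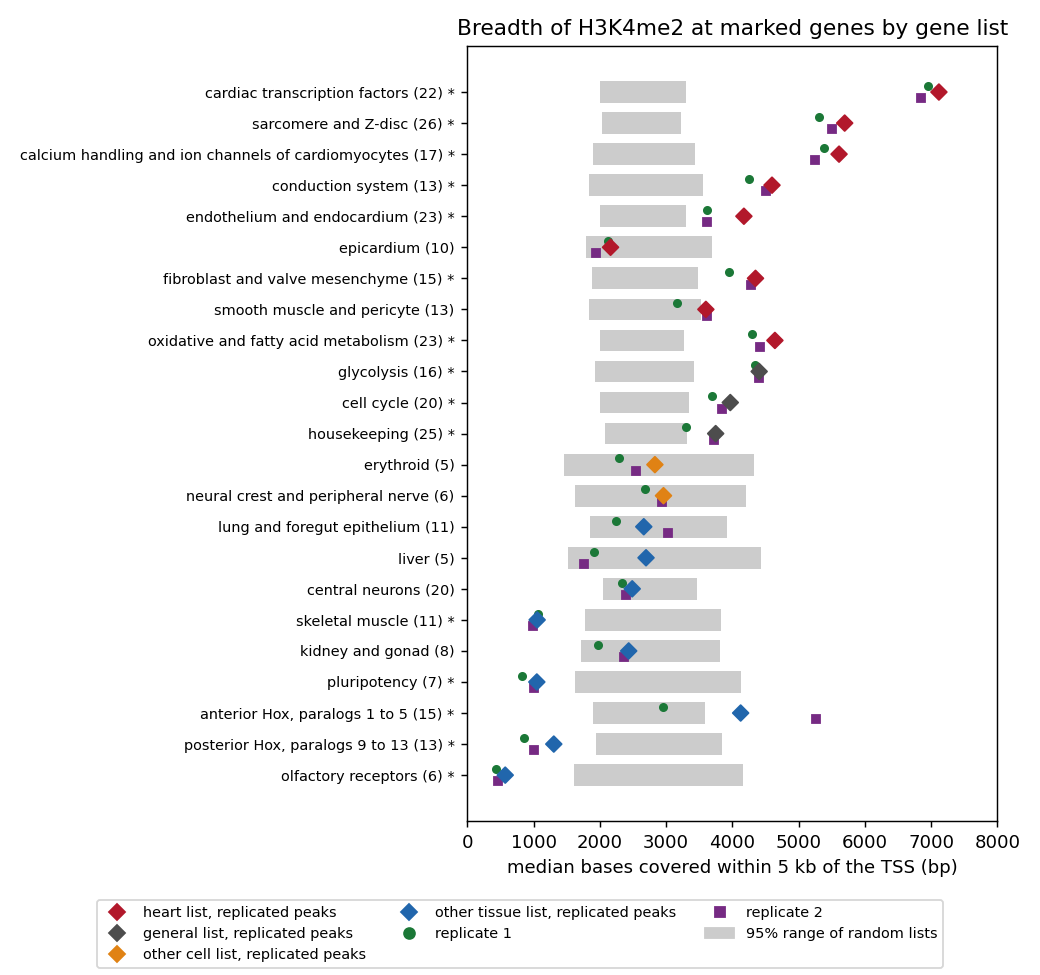
Median number of bases covered by peaks within 5 kb either side of the 5'-most TSS (x axis) for the marked members of each list, with diamonds for the replicated list, green circles for replicate 1, purple squares for replicate 2, grey bars for the 95% range of random lists and an asterisk where adjusted p was under 0.05. Cardiac transcription factors lie highest, at 7117 bases, and olfactory receptors lowest, at 572.

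Domains were made by joining replicated peaks over gaps of up to 1 kb. The widest spanned 25473 bases at Hand2, on chromosome 8 from 57311416 to 57336888. The next spanned 25462 bases at Nr2f2, a nuclear receptor of veins and atria, on chromosome 7 from 70345741 to 70371202. A domain of 23923 bases on chromosome 6 from 52156927 to 52180849 held the TSSs of Hoxa1, Hoxa2 and 5730596B20Rik. Gata4, a zinc finger regulator of cardiomyocyte genes, had 23130 bases on chromosome 14 from 63230170 to 63253299, at an inner TSS. Myh7 and the overlapping model Gm17428 had 21189, Nkx2-5 had 19314, Nfib had 18041, Meis2 had 17360, Dll4 had 16830, Tbx20 had 16497, Gata6 had 16492 and Tbx5 had 16479. Domains of this size were also found at Igf2r (21045), which clears insulin-like growth factor, at Qk (19030), an RNA-binding protein, at Bahcc1 (18368) and at Aspdh and Josd2 (18114). For Nfib and Aspdh the domain lies at an inner TSS, as for Gata4. Within 5 kb of the 5'-most TSS of Nfib 802 bases were covered in the replicated list. At the other mapped loci Myh6, the alpha myosin heavy chain, had 6103 covered bases within 5 kb (6356 ± 349 in the replicates, SD, n = 2), and the natriuretic peptide genes Nppb and Nppa had 3045 (3036 ± 14.8) and 1531 (836 ± 495). In total 126 protein-coding genes, some of which share a domain, had a domain wider than 10 kb at a TSS. Across genes the bases covered near the TSS had a Spearman's rho of 0.983 between replicates, where genes are not independent replicates.

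**Figure D4:**
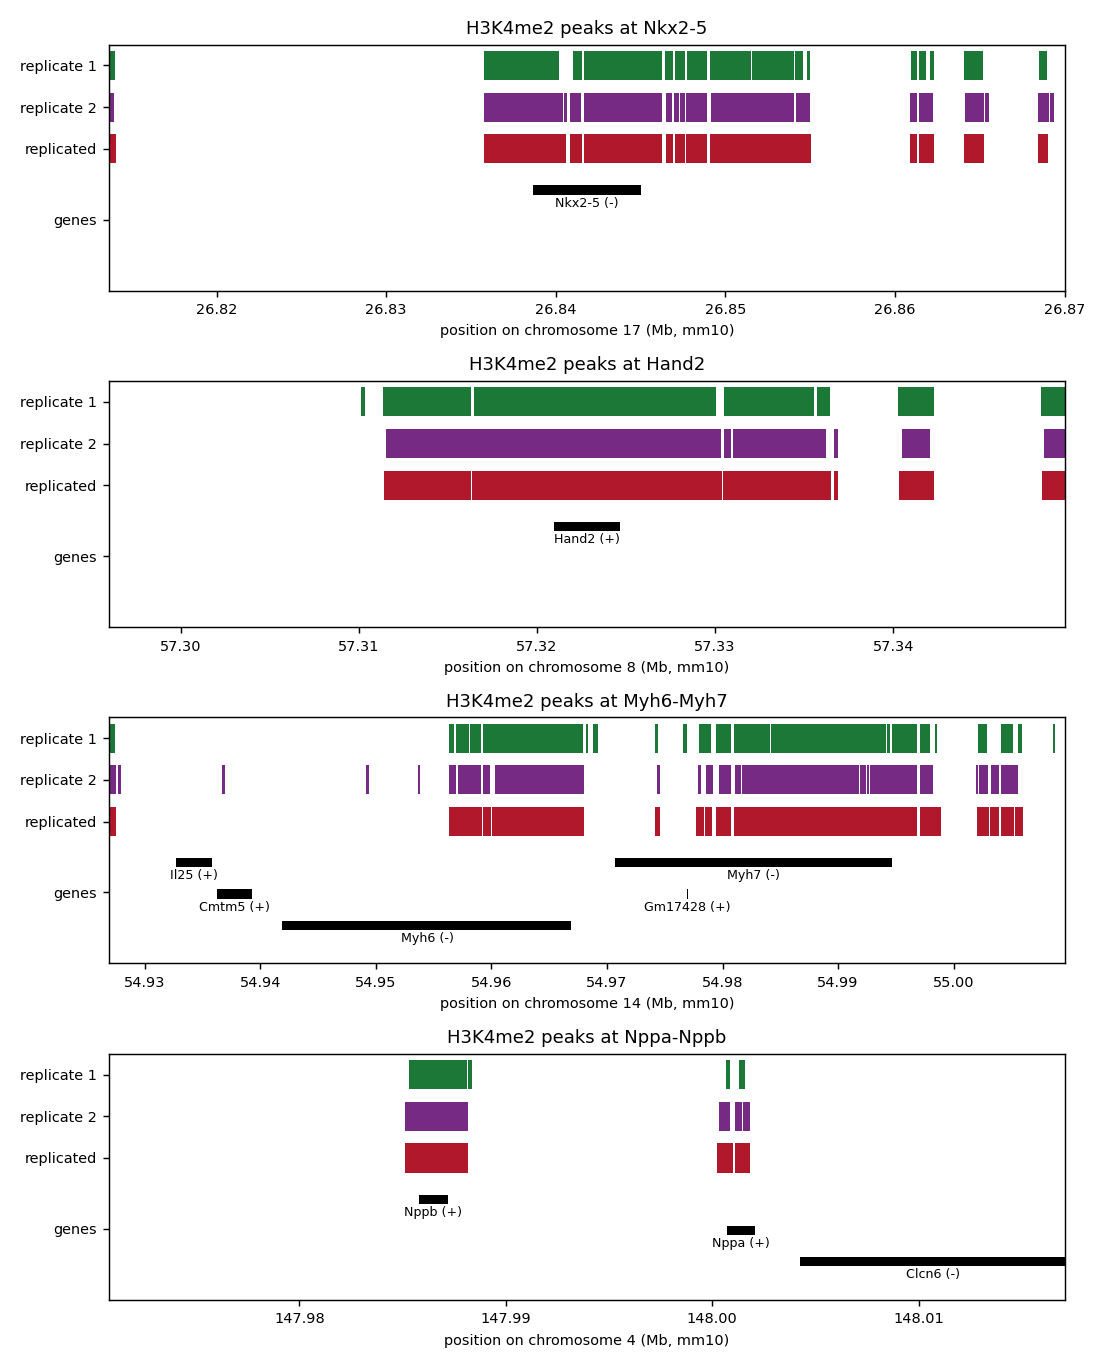
Maps of H3K4me2 peaks at Nkx2-5, at Hand2, at Myh6 and Myh7 and at Nppa and Nppb, with the position in mm10 (Mb) on the x axis and tracks of peaks for replicate 1 (green), replicate 2 (purple) and the replicated list (red) above the genes (black, strand in brackets). Peaks at Hand2 and Nkx2-5 fill domains of 25473 and 19314 bases in the replicated list, and the peaks at Nppa are short.

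Distal peaks held binding sequences of muscle regulators more often than control regions did. The MEF2 sequence, bound by activators of muscle genes, was found in 1060 of 26507 distal regions and in 139 control regions of the same GC content, a ratio of 7.63 (8.55 in replicate 1 and 6.71 in replicate 2). The sequence of the GATA factors had a ratio of 1.88, that of the TEAD factors, which act downstream of Hippo signalling, 1.67, that of SRF, a regulator of actin and sarcomere genes, 1.21 and that of NKX2-5 1.14. The sequences of TBX factors (0.867) and of HAND and related E-box factors (0.868) were less frequent than in control regions. Among general factors, CTCF, which bounds chromatin loops, had a ratio of 5.67, ETS 3.03, SP/KLF 2.84, NRF1 2.59 and AP-1 1.19. Of the factors of other tissues, REST, a repressor of neuronal genes, had 3.10 from 31 and 10 regions, RFX 1.54 and PU.1, a factor of blood cells, 1.40. The ETS, SP/KLF, NRF1 and REST sequences hold a CG, and controls were matched on GC content but not on CpG. Sequences made by shuffling the bases of MEF2 or of HAND and E-box had ratios of 1.55 to 2.08 with a fixed CG. Those without it had at most 1.31. How much of the ETS, SP/KLF, NRF1 and REST ratios CpG content accounts for was not tested. Controls also lay outside 1 kb of any annotated TSS, whereas distal peaks could lie at the TSS of a noncoding gene. How much such peaks add to any ratio was not tested either.

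A strong distal peak with a MEF2 sequence lay 92.3 kb from the TSS of Mef2c, between genes on chromosome 13 from 83744608 to 83745757, with a fold of 37.0 (31.3 and 29.5 in the replicates) and the sequence GTCCAGAGATCTAAAAATAGCCAGGCTTCG. Others lay near Meis2, on chromosome 2 from 116074550 to 116076670 with a fold of 36.5, and in an intron of Itpkb, on chromosome 1 from 180363873 to 180366463 with a fold of 30.1. The strongest with a GATA sequence, near Spocd1 on chromosome 4 from 129959506 to 129961178, had a fold of 49.8 and also held a TEAD sequence. These examples were chosen after their values were seen. Near genes were sought among protein-coding TSSs only. The hairpin of Mir9-2, a neuronal microRNA, on chromosome 13 from 83738814 to 83738885, lies nearer to that peak than Mef2c. No peak was linked to a target gene.

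By two-sided Fisher's exact tests over regions, 13 of 18 motifs were more frequent and 2 less frequent in distal peaks. Shuffled sequences could pass this exact test too: a shuffle of HAND and E-box had a ratio of 1.56 (adjusted p = 4.66e-21). The 20 shuffles of MEF2 ran from 0.709 to 2.08 and the 20 of HAND and E-box from 0.739 to 1.71. The ratios of SRF, AP-1, NKX2-5, TBX and HAND and E-box lie within 0.709 to 1.31, the range of the shuffles without a fixed CG. Those of GATA, TEAD, RFX and PU.1, whose sequences hold no CG, lie above 1.31. They lie under the 2.08 of a shuffle with a CG. No other motif was shuffled, so a call alone does not tell a motif from its bases. Adjusted p was 3.07e-178 for MEF2, 4.09e-97 for CTCF, 3.76e-90 for GATA, 9.9e-86 for TEAD, 0.000198 for NKX2-5, 0.000809 for SRF, 6.91e-17 for HAND and E-box and 0.0129 for TBX. HNF1 (1 and 0 regions), OCT-SOX (5 and 3) and HNF4A (175 and 165) did not pass, although OCT-SOX passed the exact test in replicate 1 (ratio 8, adjusted p = 0.0439) and in whole peaks. Without GC matching the ratio turned to 0.835 for NKX2-5, 0.870 for SRF and 1.11 for TBX, REST and SRF were lost among peaks with a fold of at least 3, SRF was lost in the pooled list, and REST (ratio 1.06), SRF, AP-1, NRF1 and RFX were lost in regions with under 10% of repeat-masked bases.

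**Figure D5:**
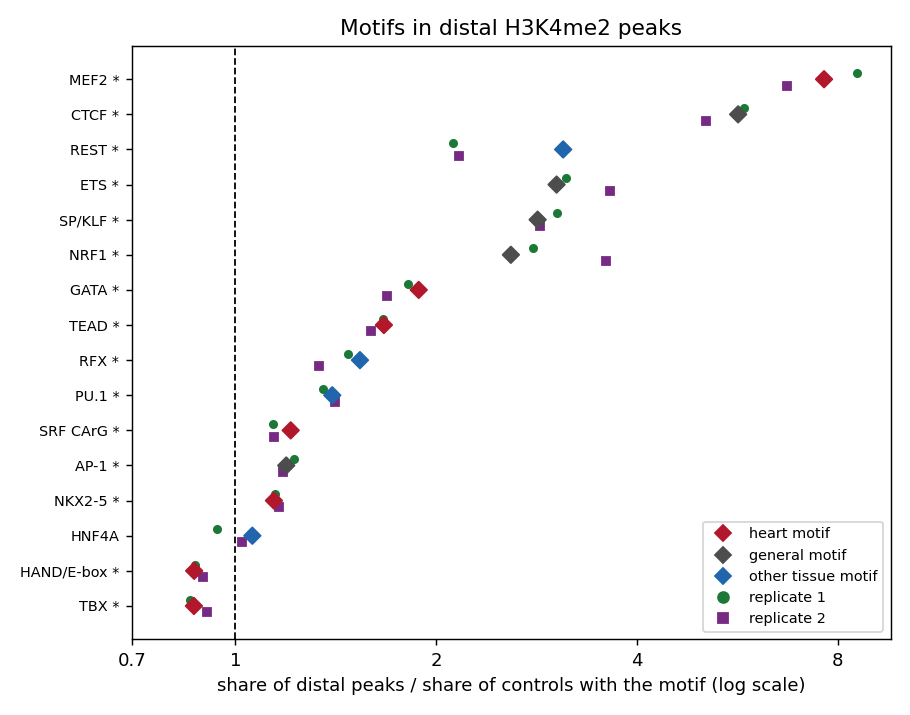
Ratio of distal peaks to GC-matched control regions that hold each binding sequence (x axis, log scale, with a dashed line at a ratio of 1), with diamonds for the replicated list, green circles for replicate 1, purple squares for replicate 2 and an asterisk where adjusted p was under 0.05. MEF2, at 7.63, and CTCF, at 5.67, lie highest, and HNF1 and OCT-SOX are left out because few regions held them.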

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

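The counts in this part were chosen only after the main results were seen. The replicated list held 13 peaks on 6 unplaced scaffolds, which no comparison used, with a median fold of 10.3, and replicate 1 had 14 such peaks and replicate 2 had 13. Of the lincRNA genes over 2 kb from a protein-coding TSS, which the comparisons of protein-coding promoters left out, 879 had a replicated peak within 1 kb of their own TSS. The pooled list held 16143 peaks that were missing from the replicated list, with a median fold of 2.68 against 8.03 in the replicated list.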

How the results depend on the processing

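Tests chosen only after the data were seen were those with genes lacking another TSS within 2 or 10 kb, with random lists matched on CpG ratio and with regions low in repeats. No paired analysis was possible because the labels give only 1 group. Among genes with no other TSS within 10 kb, breadth could not be tested for erythroid, liver, anterior Hox, posterior Hox and olfactory receptor genes, which had fewer than 5 marked members. Overlap and correlation need both replicates, so leaving out a replicate was not possible for them. In each case below the cause was not tested. With CpG matching, fully marked lists whose matched lists also reached 100% could not be called higher. The mean share of shared peaks fell to 63.0% at 75% of the peak and to 63.2% at 50% reciprocal overlap, and lay between 76.9% and 80.3% under the other alternatives. Rho was 0.919 with a fold of at least 3, 0.918 with a −log10 p of at least 5, 0.924 at 50% overlap and 0.937 from −log10 p. The share of peaks near a TSS was 32.8% in the pooled list, 38.6% and 46.6% with windows of 500 and 2500 bases, 31.9% with 1 TSS per gene and 34.6% to 37.1% in single replicates. Genes with a promoter peak numbered between 14432 and 15498 under all alternatives run, 15178 to 15392 of them in single replicates. Lists called on promoter peaks numbered 14 with 1 TSS per gene, 11 with CpG matching and 16 to 18 in single replicates, lists called on breadth 9 within 2 kb, 13 within 10 kb, 10 of 18 among genes with no other TSS within 10 kb, 17 in the pooled list and 14 to 16 in single replicates. Motifs above controls numbered 8 in regions low in repeats, 11 with a fold of at least 3 and without GC matching, 12 in the pooled list and 13 to 14 in single replicates. Changes of direction in promoter share were found for epicardium without replicate 2 (69.2%, against 84.6% without replicate 1), lung with 500 bases (64.3%), kidney and gonad with 2500 bases (83.3%) and with CpG matching (66.7%), and posterior Hox with CpG matching (81.25%, adjusted permutation p = 0.0491). In breadth they were found for neural crest with a fold of at least 3 or a −log10 p of at least 5 (2645.5 bases in each) and within 2 kb (2149.5), and for liver in the pooled list (1130, adjusted permutation p = 0.00828), in single replicates (1764.5 to 1917), within 2 kb (2139) and within 10 kb (2697). They were also found for lung without replicate 1 (3022, against 2243 without replicate 2), without matching or with GC or CpG matching (2663) and among genes with no other TSS within 10 kb (2930), for erythroid genes without replicate 2 (2285, against 2540.5 without replicate 1) and within 2 kb (1666), and within 2 kb for smooth muscle (2175) and anterior Hox (2226). For kidney and gonad they were found within 10 kb (3070.5), with CpG matching (2435.5) and among genes with no other TSS within 10 kb (2898), and for central neurons under the last pair of alternatives (2488.5 and 2489). In motifs they were found for HNF4A without replicate 2 (0.939, against 1.02 without replicate 1) and in regions low in repeats (0.863), and without GC matching for NKX2-5 (0.835), SRF (0.870), TBX (1.11) and OCT-SOX (0.556). Of the other values, 228 promoter shares, 208 breadths and 118 motif ratios kept their direction and their side of the threshold, 16, 12 and 8 lost the call, and 1, 6 and 2 gained it. Bases covered at named genes stayed within 1 SD between replicates in 458 cases and moved beyond it in 157. Depth is unknown, so it cannot be said which missing peaks it accounts for.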

Other observations

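The microRNA list, the noncoding classes, the distal counts and the test of promoter fold at neuronal genes were chosen only after the main results were seen. A peak lay within 1 kb of 3 of 7 hairpins of muscle microRNAs, of 2 of 2 of smooth muscle, of 1 of 1 of endothelium and of 3 of 3 of neurons, and no test was run on these groups. Within 5 kb of the hairpin, peaks covered 9402 bases at Mir1a-1, 3411 at Mir1a-2 and 2713 at Mir133a-1, all muscle microRNAs, 6765 at Mir143 and 6084 at Mir145a of smooth muscle, and 5408 at Mir126a of endothelium, which lies 77 bases from a protein-coding TSS, so its peak cannot be told from that promoter's. The hairpins of Mir206 of skeletal muscle, Mir122 of liver, Mir451a of erythroid cells and Mir223 of myeloid cells had 0 covered bases, but Mir124a-1 and Mir9-2 of neurons had 3866 and 2520. The muscle hairpins without a peak within 1 kb were Mir133a-2 (1159 bases within 5 kb), Mir208b (2975) and Mir208a and Mir499 (0 each in the replicated list, but 454 at Mir208a in replicate 2 and 200 at Mir499 in replicate 1), and a hairpin is not an annotated promoter. Among lincRNA genes over 2 kb from a protein-coding TSS, 16.4% had a peak within 1 kb of their TSS (17.3% ± 1.28 in the replicates, SD, n = 2), against 5.34% in random placements, and processed pseudogenes had 2.94% against 5.56%.

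Distal peaks were more numerous around genes of 3 of the 9 heart lists and around anterior Hox genes. A peak over 1 kb from a TSS counted as distal even inside a domain that spans the TSS, as at Hand2 and Nkx2-5. These lists also had wide marks, so the counts are not separate from breadth. Within 50 kb of the TSS the median was 5 distal peaks at cardiac transcription factors, 4 at sarcomere genes, 5 at calcium handling and ion channel genes and 6 at anterior Hox genes, the 4 of 23 lists that passed a permutation test against random lists of marked genes. Neighbouring Hox genes count the same distal peaks, whereas random lists draw genes independently. The anterior Hox call thus rests on fewer independent places than genes. The conduction system, endothelium, epicardium, fibroblast, smooth muscle and oxidative metabolism lists did not pass. Qk had the most of all protein-coding genes (27), followed by Actn2, which encodes the actinin of the Z-disc, and Igf2r (17 each). By paralog number the median covered bases in HoxA fell from 5969.5 at 1 to 4 to 4125 at 5 to 8 and 1243 at 9 to 13. In HoxB they fell from 4737 to 4366 and 1222. In HoxC the medians were 1344, 548 and 548, and in HoxD 1865, 1757 and 1518. This order was not tested. The 5'-most TSS of some Hox genes lies at another paralog. That of Hoxa3 lies between those of Hoxa6 and Hoxa7, and that of Hoxc5 lies 647 bases from that of Hoxc10. The HoxC value of 548 at 5 to 8 is that of Hoxc5, so it describes a place at Hoxc10. An order by paralog number is thus not strictly an order along the cluster. Chromosome X had 6.32 replicated peaks per Mb and 53.8% of genes marked, and chromosome 11 had 27.8 peaks per Mb. On chromosome Y, Uty and Ddx3y had promoter peaks in both replicates, and Eif2s3y had one in replicate 2 (788 covered bases) and none in replicate 1 (0 covered bases).

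The design gives 1 group, so no biological explanation was tested by a comparison of groups. The wide marks at cardiac transcription factors, sarcomere genes and ion channel genes could come from CpG-rich promoters or from promoters of neighbouring genes in the window. Both were tested on these 3 lists. Against random lists matched on CpG ratio, 3 of 3 lists stayed wider past the threshold, and among genes with no other TSS within 10 kb, again 3 of 3 did, so neither accounts for the whole pattern. Within 2 kb the ion channel list was no longer called, so that part of the pattern rests on bases beyond 2 kb.

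The promoter peaks at central neuron genes may reflect CpG-rich promoters. Random lists of the same CpG ratio had 82.2% marked genes on average and 68.2% to 90.9% in 95 of 100 lists, a range that reaches the 90.9% of the neuron genes. Neighbouring promoters were argued against, since among genes with no other TSS within 2 kb the neuron genes stood 25.2 percentage points above other genes. A small share of neurons in the tissue stays open: the median promoter fold of 24.9 lay at percentile 3.87 of matched lists (24.3 to 37.4), neither below nor clear of their range. Snap25 and Syt1, abundant in neurons, had folds of 17.3 and 46.7 and Slc17a6 had no peak, and how many of these genes the heart expresses was not measured.

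The high ratio of the MEF2 sequence and the low ratio of the HAND and E-box sequence in distal peaks could come from the bases of the sequence or from repeats in the control regions. The highest ratio of 20 shuffled MEF2 sequences was 2.08, against 7.63 for MEF2, and in regions with under 10% of repeat-masked bases the MEF2 ratio was 8.12, which argues against both. For HAND and E-box the ratio in such regions was 0.871, which argues against repeats. Of its 20 shuffled sequences 4 had a ratio as low, with a range of 0.739 to 1.71, so its bases and a true depletion cannot be told apart with 20 shuffles.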
